A study of Mus musculus with 20 samples.

How the data were processed

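RNA sequencing was performed on 20 mouse libraries, 14 from total liver and 6 from RAW264.7 cells, a mouse macrophage-like line. Per the labels, the liver libraries fell into 4 groups, WT on control diet (n = 4), WT on alcohol diet (n = 4), RageΔMye on control diet (n = 3) and RageΔMye on alcohol diet (n = 3), with 6 weeks of feeding. The RAW264.7 libraries fell into cells given BSA (n = 3) and cells given a complex of [O] HMGB1 and IL1β (n = 3), with 6 hours of treatment. Libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols, and the genome build was mm10, per the submitters' processing notes. The aligner, the counting tool, its strand setting and the gene annotation are not given in the sources used here. Nothing in the labels says that the replicates came from separate animals or separate cultures.

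The authors deposited 2 tables, 1 for liver and 1 for RAW264.7 cells, with 24972 gene symbols each and 1 column per library. The table headers name no unit. The values were read as TPM made by the authors before they were deposited, because they were not whole numbers and every column summed to the same total. The choice of tests for either counts or normalised values was written down before the data were examined, and the tests for normalised values were the ones that this unit needed. The number of reads behind a TPM value is unknown, so no interval from counting error is given. All columns were used. No difference between a liver value and a RAW264.7 value was tested, and the tables were set side by side only through genes called in both, genes above set levels and shares of TPM.

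Values were transformed to log2(TPM + 1), and genes with a mean of at least 1 TPM in at least 1 group of the table were tested. Differences were tested with limma 3.58.1 in R 4.3.3, with its intensity trend, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison. A gene passed at an adjusted p under 0.05. The 14 liver libraries were fitted together with 1 mean per group, from which came the effect of alcohol in each genotype, the effect of genotype on each diet and the difference of the alcohol effect between genotypes. The 6 RAW264.7 libraries were fitted on their own, which made 6 comparisons in all. The grouping, the tests, the gene lists and the rule for naming genes were fixed before the data were examined.

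Of 40 gene lists covering metabolic pathways, inflammatory responses and cell type markers, 34 in liver and 16 in RAW264.7 cells held at least 5 tested genes and were tested with camera of limma at its preset correlation of 0.01. List p-values were adjusted by Benjamini-Hochberg within a comparison, and each list was tested again with a correlation estimated from the residuals. Genes called in both of a pair of comparisons were counted per direction and compared with the number that independent lists would share, by Fisher's exact test, one-sided.

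The genes named are the 7 that the labels name or point at (Ager, Hmgb1, Il1b, Il1r1, Il1rap, Il1rn, Tlr4), then the 10 largest rises and 10 largest falls in WT liver and in RAW264.7 cells and the 5 and 5 largest elsewhere. Those had to pass the test, reach a mean of 1 TPM, show no overlap between libraries (except for the difference of effects) and not carry a predicted-gene name. Added to them are up to 4 passing members of each list with the smallest adjusted p, or else the 2 with the smallest p as values only. Some genes that this rule selects are not reported here, and the counts of named genes and of their far samples leave them out. Any other gene is said to have been chosen after its values were seen.

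Alternatives written before the data were examined were pseudocounts of 0.1 and 0.01, no filter on low values, a filter at 5 TPM, an added 2-fold minimum, an adjusted p under 0.01, omission of each library in turn, a fit of only the 2 groups compared, the sample number as a block, and other correlations and tests for the lists. Chosen after seeing the data were a fit without genes that overlap exons on the opposite strand, the same with TPM rescaled over the genes left, quantile normalization, and library weights estimated per genotype. For the overlaps, symbols were matched to GENCODE vM21, which placed 24493 of 24970 symbols, and 5932 of these had an exon that overlapped an exon of a gene on the opposite strand.

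The fits were tested on simulated data with 200 changed genes per comparison, at 2-fold, 4-fold and 8-fold. When every group had the same spread, between 2.15% and 8.82% of the calls of the fits to all libraries of a table were false. When each group was given its own measured spread, the joint fit of the liver libraries called 102 genes in WT liver on alcohol, of which 1.96% were false, and 859 genes in RageΔMye liver on alcohol, of which 87.2% were false. In the latter comparison a fit of the 6 RageΔMye libraries alone called 5 simulated genes, none of them false, and recovered 7.14% of the 8-fold changes. With these spreads 74.9% and 76.2% of the genotype calls on alcohol and control diet (328 and 359 genes) and 77.4% of the calls for the difference of effects were false, and 16.1% in RAW264.7 cells. In RAW264.7 cells the fit recovered 4.08%, 24.3% and 39.4% of the 2-fold, 4-fold and 8-fold changes. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.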

Results

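Gene expression was measured in livers of mice on alcohol or control diet and in RAW264.7 cells exposed to a complex of [O] HMGB1, the oxidised form of an alarmin, and IL1β. Values are given below as mean TPM ± SD, with n = 4 per WT liver group and n = 3 in every other group. The labels name the second genotype RageΔMye, read here as a loss of Ager, the gene of the receptor RAGE, in myeloid cells. The deposited values do not reveal how many reads each library holds. WT libraries listed 15113 to 15599 genes above 0, libraries labelled RageΔMye 7596 to 8502, and RAW264.7 libraries 8630 to 9231. The most frequent value above 0 was 0.0576 to 0.0835 TPM in WT libraries, 14.4 to 20.5 TPM in libraries labelled RageΔMye and 9.85 to 13.4 TPM in RAW264.7 libraries. Of 14 housekeeping genes, 1 to 4 were listed at 0 in each library labelled RageΔMye, 0 to 2 in each RAW264.7 library and none in WT. A 0 in libraries labelled RageΔMye or in RAW264.7 libraries is therefore reported as listed at 0, not as absence. Correlations between replicates across genes were 0.977 to 0.993 in WT, 0.771 to 0.802 in libraries labelled RageΔMye and 0.810 to 0.833 in RAW264.7 cells. The median SD on the log2 scale was 0.142 to 0.189 in WT groups, 0.675 to 0.692 in groups labelled RageΔMye and 0.565 to 0.575 in RAW264.7 groups.

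Ager itself went against the genotype label. It was listed at 0.199, 0.153, 0.0194 and 0.105 TPM in the WT control libraries and at 0.133, 0.0378, 0.478 and 0.125 TPM in the WT alcohol libraries. In the libraries labelled RageΔMye it was listed at 124, 101 and 128 TPM on control diet and at 112, 93.1 and 166 TPM on alcohol diet. It was listed at 0 in all 6 RAW264.7 libraries. The gene lies on mm10 chromosome 17, at 34597862 to 34600936 on the plus strand. Genes with an exon that overlaps an exon on the opposite strand held 15.4% to 18.3% of the TPM in WT libraries, 57.8% to 63.7% in libraries labelled RageΔMye and 72.3% to 76.1% in RAW264.7 libraries. Directions that involve the genotype are therefore given for the libraries as labelled.

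**Figure D1:**
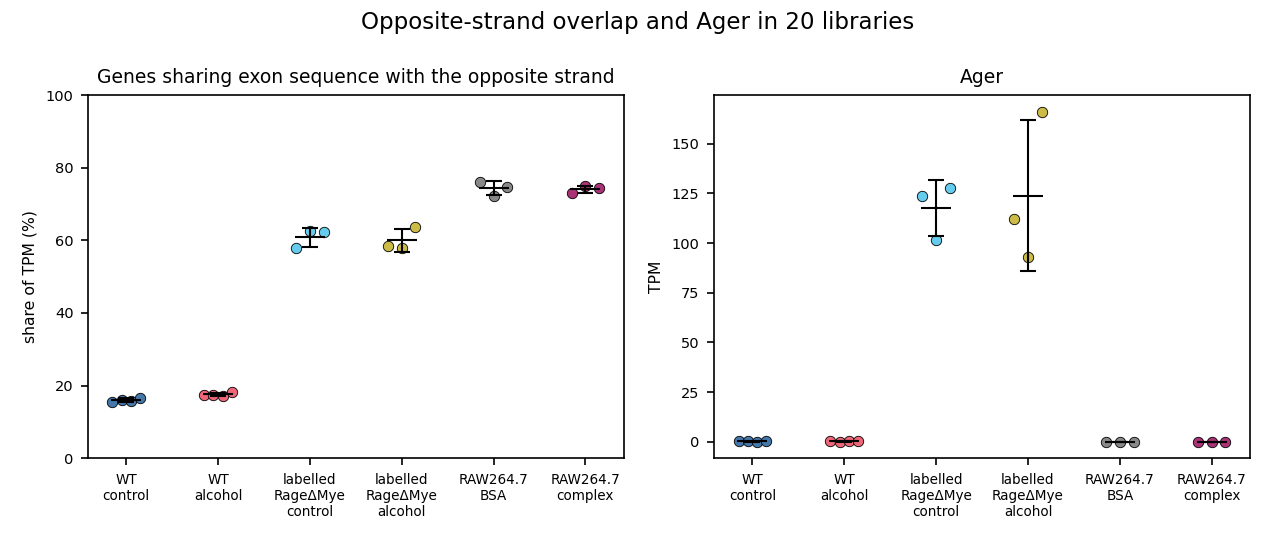
Share of TPM (%) held by genes whose exons overlap exons on the opposite strand, and TPM of Ager, in the 20 libraries by group. Points are libraries and bars are mean ± SD. The overlap share reaches at most 18.3% in WT and at least 57.8% elsewhere, and Ager reaches at most 0.478 TPM in WT and at least 93.1 TPM in libraries labelled RageΔMye.

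The first comparison asked what the alcohol diet changed in WT liver. The largest changes were in genes whose hepatic expression differs between the sexes. Mup20, a major urinary protein gene on chromosome 4, fell from 16930 ± 6147 to 53.5 ± 4.15 TPM (log2 fold change -8.21, SE 0.305, adjusted p = 1.9e-08). Cyp2c69, a cytochrome gene, rose from 0.971 ± 0.712 to 285 ± 43.7 TPM (7.24, SE 0.252, adjusted p = 1.7e-08). Among the other large falls were the urinary protein genes Mup7 (-11.97), Mup14 (-11.81), Mup11 (-10.55), Mup1 (-8.62) and Mup12 (-8.38). Also among them were the cytochromes Cyp4a12a (-7.95), Cyp2d9 (-6.41) and Cyp4a12b (-6.23), and the steroid dehydrogenase Hsd3b5 (-6.22). Among the other large rises were the cytochromes Cyp2a4 (9.74), Cyp3a41a (8.82), Cyp2b9 (7.55) and Cyp2b13 (7.34). Beside these rose the sulfotransferases Sult2a2 (8.42) and Sult2a1 (8.11), A1bg (6.77) and the hepcidin gene Hamp2 (6.76). Of the female-biased liver genes 15 of 18 rose, and all 18 did when adjusted over the list alone (camera adjusted p = 4.9e-55, and adjusted p = 2.1e-04 with an estimated correlation). Of the male-biased liver genes 16 of 17 fell, and all 17 when adjusted over the list alone (adjusted p = 1.3e-49, and adjusted p = 9.8e-04 with an estimated correlation). The sex-linked transcripts, chosen after their values were seen, differed between the same groups. Xist, transcribed from the inactive X chromosome, was at 0.00165 to 0.135 TPM in the WT control libraries and at 17.8 to 27.3 TPM in the WT alcohol libraries. The sum of 4 Y-linked genes was 11.3 to 16.6 TPM and 0 to 0.0161 TPM, although all liver libraries are labelled male.

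**Figure D2:**
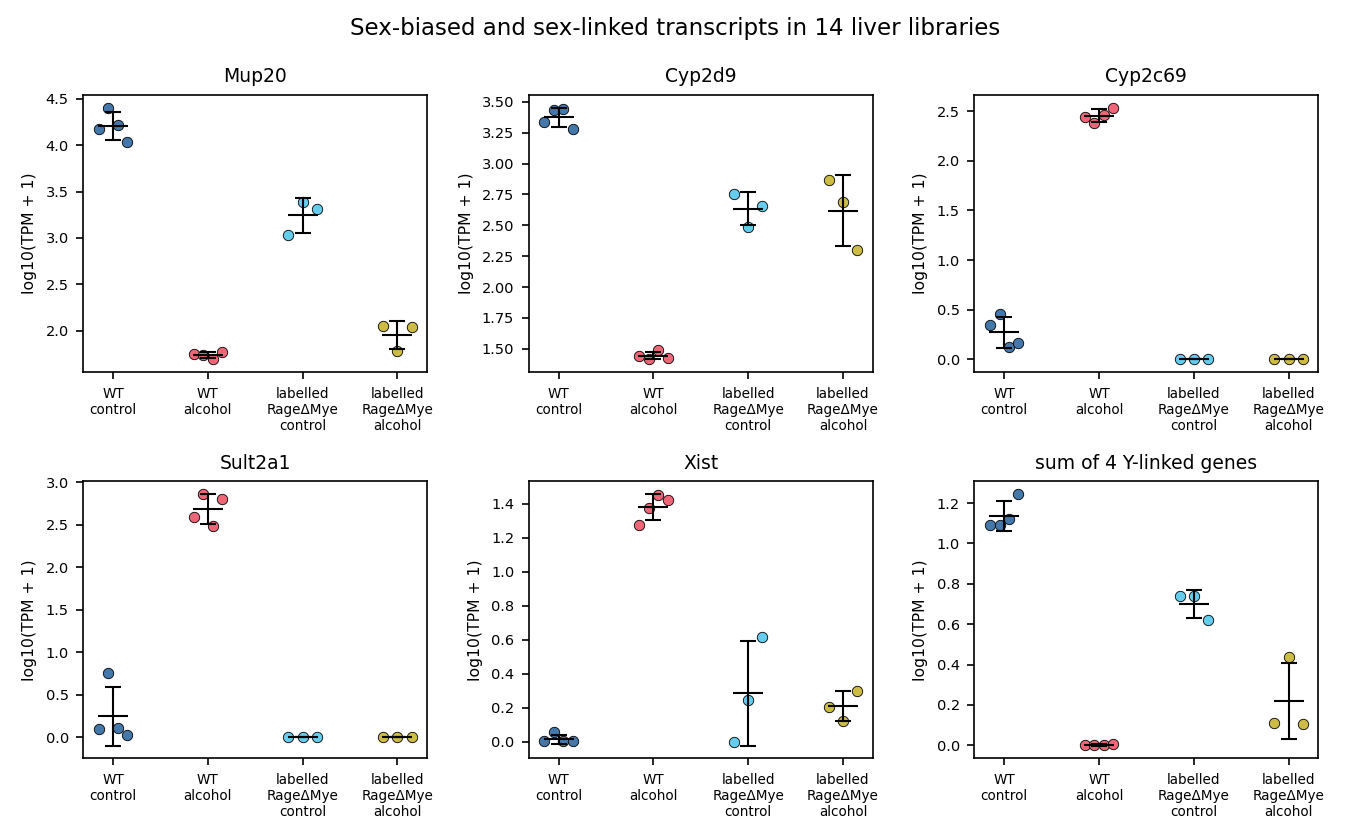
Sex-biased genes, Xist and the sum of 4 Y-linked genes as log10(TPM + 1) in the 14 liver libraries by group, with points for libraries and bars for mean ± SD of the log values. The WT alcohol libraries lie at 17.8 TPM or more for Xist and at 0.0161 TPM or less for the Y-linked sum, and the WT control libraries lie on the other side for both.

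Inflammatory and matrix genes moved in the same WT libraries, those that differ in Xist and in the Y-linked sum. The interleukin-1 receptor antagonist gene Il1rn rose from 1.19 ± 0.251 to 9.86 ± 4.43 TPM (log2 fold change 2.21, SE 0.537, adjusted p = 0.0495). The decoy receptor gene Il1r2 rose from 1.26 ± 0.482 to 5.67 ± 1.23 TPM (1.57, SE 0.200, adjusted p = 8.2e-04). Il1r1 was at 73.9 ± 9.77 against 27.5 ± 11.6 TPM (1.48, adjusted p = 0.261), Il1rap at 10.5 ± 3.17 against 16.0 ± 2.48 TPM (-0.60, adjusted p = 0.215). Il1b was at 8.79 ± 2.02 against 5.20 ± 1.40 TPM (0.66, adjusted p = 1), Hmgb1 at 24.6 ± 4.14 against 23.6 ± 2.18 TPM (0.05) and Ager at 0.193 ± 0.195 against 0.119 ± 0.0769 TPM (0.08). In a fit of the 8 WT libraries alone Il1r1 (adjusted p = 0.00293), Il1b (0.0296) and Il1rap (0.0374) passed, and Hmgb1 did not. Tlr4 was under the level for testing in every group, at 0.108 to 0.188 TPM in WT libraries, 0 to 0.375 TPM in libraries labelled RageΔMye and 0 to 0.860 TPM in RAW264.7 libraries. Of the HMGB1 and IL-1 receptors and ligands 3 of 25 rose, the third being Irak3 (0.81), and 4 did when adjusted over the list alone (camera adjusted p = 3.3e-06, and 0.00451 with an estimated correlation). Acute-phase genes were higher as a list, with 5 of 26 past the test and 13 higher and 1 lower when adjusted over the list alone. Among them were Hamp (6553 ± 1112 against 2624 ± 382 TPM), the metalloreductase Steap4 (3.09) and the fibrinogen genes Fgg (1.30) and Fgb (1.20). Its camera adjusted p was 7.2e-12, and adjusted p = 0.126 with an estimated correlation.

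Matrix lists were higher with both correlations. In the fibrillar matrix and stellate cell list 2 of 30 rose, Thbs1 (0.87) and Postn (0.87), and 6 when adjusted over the list alone (camera adjusted p = 1.3e-10, and 0.00970 with an estimated correlation). Of the matrix proteases and inhibitors 2 of 20 rose, Ctsl (0.71) and Adamts1 (0.82), with 5 higher and 1 lower when adjusted over the list alone (1.5e-07, and 0.00216 with an estimated correlation). The immediate-early genes (1 of 15 rose, Klf6, 1.52, and 5 over the list alone), the NF-kB targets (1 of 17, Irak3, and 4) and the T and NK cell markers (2 of 7, Gzma, 1.14, and Gzmb, 0.62, and 3) were higher as lists. Their camera adjusted p was 3.6e-09, 4.0e-06 and 3.7e-05, and 0.0262, 0.0149 and 0.0232 with an estimated correlation. The monocyte-derived macrophage markers were higher as a list without a single passing member of 15 (1 when adjusted over the list alone), with Cd14 at 59.7 ± 31.2 against 7.99 ± 2.24 TPM (adjusted p = 0.278). In the fit of the 8 WT libraries alone Cd14 (adjusted p = 2.6e-04) and S100a4 (0.00842) passed. The list p was 2.9e-04, and 0.0206 with an estimated correlation. Neutrophil markers (1 of 9 rose, Ngp, 1.55, and 4 over the list alone) had a camera adjusted p = 3.6e-05, and adjusted p = 0.0613 with an estimated correlation.

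Of the bile acid genes 3 of 20 fell, the transporter Slco1a1 (-4.59) and the hydroxylases Cyp7b1 (-3.70) and Cyp8b1 (-2.74), with 5 lower and 1 higher when adjusted over the list alone (camera adjusted p = 4.4e-04, and adjusted p = 0.0845 with an estimated correlation). Of the PPAR-alpha targets 3 of 29 rose, Acot2 (2.46), Acot3 (1.79) and Pdk4 (2.51), and 4 when adjusted over the list alone (0.0158, and adjusted p = 0.376 with an estimated correlation). Of the drug-metabolising cytochromes 2 of 19 rose, Cyp2a4 and Cyp2c37 (1.18), and Cyp2c54 fell (-2.07), with 7 higher and 2 lower when adjusted over the list alone (0.0129, and adjusted p = 0.168 with an estimated correlation). Slco1a1 is also on the male-biased list, and Acot3 and Cyp2a4 are on the female-biased list. Diet and sex cannot be told apart in these 3 lists, since the WT diet groups also differ in Xist and in the Y-linked sum. The list of ER stress genes was higher (0.00176, and adjusted p = 0.156 with an estimated correlation), although its only passing member of 24, the asparagine synthetase gene Asns, fell from 21.5 ± 11.8 to a mean of 0.857 TPM. Adjusted over the list alone 4 were higher and 1 lower. Further lists higher only at the preset correlation were the sinusoidal endothelial markers (1 of 16, Lyve1, 1.64, adjusted p = 0.239 with an estimated correlation), the interferon-stimulated genes (1 of 29, Gbp3, adjusted p = 0.142 with an estimated correlation) and the cytokines and chemokines (2 of 19, Ccl5, 0.79, and Il1rn, adjusted p = 0.105 with an estimated correlation). The same held for the inflammasome genes (1 of 10, Casp4, 0.90, adjusted p = 0.154 with an estimated correlation), glycolysis and hypoxia genes (0 of 22, adjusted p = 0.175 with an estimated correlation) and cholangiocyte markers (0 of 6, adjusted p = 0.244 with an estimated correlation).

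The remaining lists did not pass in WT liver. Among their members the lipid droplet genes Plin2 rose from 704 ± 342 to 1852 ± 480 TPM (1.45) and Cd36 rose from 7.19 ± 4.28 to 28.1 ± 6.26 TPM (1.93), while Cidea fell (-2.20). The Kupffer cell list held 1 fall of 13, C6 (191 ± 28.4 to 8.20 ± 1.73 TPM), and its median of 0.11 and mean of -0.28 differed in sign. The medians and means also differed in sign for hepatocyte markers (-0.01 and 0.10) and for NRF2 and glutathione genes (-0.02 and 0.01), of which Gstp1 fell from 2969 ± 855 to 278 ± 19.7 TPM and Abcc4 rose (1.20). Of the genes of alcohol and acetaldehyde oxidation 1 of 13 fell, Aldh1a1, from 1038 ± 137 to 564 ± 134 TPM (-0.90, camera adjusted p = 0.383). Of the methionine and one-carbon genes 1 of 15 fell, Bhmt (-1.11, camera adjusted p = 0.0513).

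In all, limma called 337 of 12069 genes in WT liver, 173 higher and 164 lower. No overlap between the libraries of the 2 diets was seen for 3334 genes (27.6%), against 2.86% by chance. The joint fit lends these libraries the wider spread of the others, and a fit of the 8 WT libraries alone called 3042 genes, which included all 337. Without WT control replicate 3 the count was 164, and without WT alcohol replicate 1 it was 171.

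**Figure D3:**
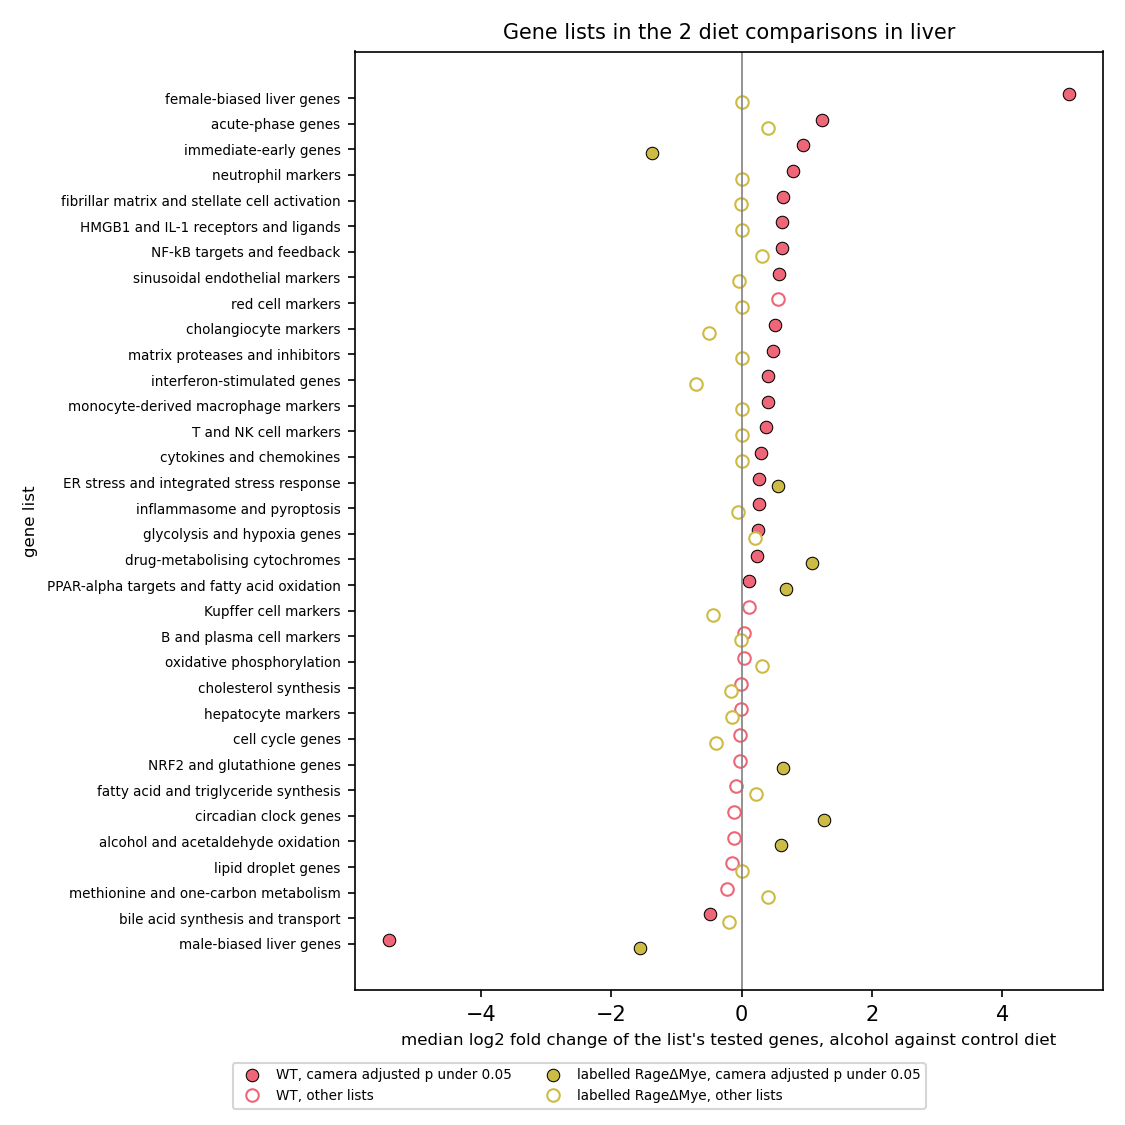
Median log2 fold change, alcohol against control diet, of the tested genes of the 34 gene lists in WT liver and in liver of animals labelled RageΔMye. Filled points passed camera at the preset correlation. The female-biased list has a median of 5.02 in WT and 0 in libraries labelled RageΔMye, and the drug-metabolising cytochromes have medians of 0.24 and 1.08.

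The same diet was compared in the libraries labelled RageΔMye. The SE, p-values, calls and list counts in this and the next paragraph come from the joint fit, which lends these libraries the narrower spread of WT. In simulated data with each group's own spread 87.2% of its calls here were false. Fits without the WT libraries or with library weights are given after these 2 paragraphs. Cyp2a5, a cytochrome gene, rose from 59.5 ± 46.6 to 1941 ± 257 TPM (log2 fold change 5.50, SE 0.582, adjusted p = 8.3e-05). The cytochrome reductase gene Por rose from 39.2 ± 5.53 to 177 ± 34.9 TPM (2.14, SE 0.191, adjusted p = 1.8e-05). Cyp4a14, a fatty acid hydroxylase, was listed at 0 in the 3 control libraries and rose to 197, 258 and 80.7 TPM in the alcohol libraries. Cyp2a4 (mean 352 ± 374 TPM), Rgs16 (61.2 ± 45.2 TPM) and the ER chaperone gene Creld2 (57.4 ± 41.3 TPM) likewise rose from controls listed at 0. Mup20 fell from 1859 ± 711 to 92.0 ± 28.9 TPM (-4.29, SE 0.352, adjusted p = 9.0e-06), and Mup14 (-8.51), Mup11 (-7.39), Hsd3b5 (-6.03) and the elongase gene Elovl3 (-5.34) fell too. Pitx3, whose exons overlap those of Elovl3 on the opposite strand, went from 56.3 ± 9.38 TPM to 0 in all 3 libraries. The 4 Y-linked genes summed to 3.16 to 4.50 TPM in the control and 0.276 to 1.74 TPM in the alcohol libraries, and Xist was at 0 to 3.10 TPM. None of Hmgb1 (32.1 ± 3.10 against 30.6 ± 7.04 TPM), Ager (0.04), Il1rap (680 ± 112 against 839 ± 32.9 TPM, adjusted p = 0.417), Il1r1 (2.40 ± 3.13 against 1.16 ± 1.01 TPM), Il1b (4.08 ± 7.07 against 5.81 ± 10.1 TPM) or Il1rn (listed at 0 against 1.93 ± 3.33 TPM) passed.

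Of the drug-metabolising cytochromes 8 of 19 rose and 1 fell, with 13 and 1 when adjusted over the list alone (camera adjusted p = 7.3e-08, and adjusted p = 0.0636 with an estimated correlation), among them Cyp2c29 (210 ± 11.9 against 43.9 ± 7.86 TPM). Of the male-biased genes 6 of 17 fell, and 9 when adjusted over the list alone, with Selenbp2 at -4.32 (7.2e-07, and adjusted p = 0.411 with an estimated correlation). NRF2 and glutathione genes had 4 of 26 higher, among them Gstm1 (2503 ± 931 against 397 ± 52.2 TPM) and Gsta3 (1.35), and 6 when adjusted over the list alone (0.0030, and adjusted p = 0.515 with an estimated correlation). Alcohol and acetaldehyde oxidation had 3 of 13 higher, Adh1 (1578 ± 92.0 against 605 ± 171 TPM), Aldh1a1 (1.30) and the ethanol-oxidising cytochrome Cyp2e1 (3750 ± 843 against 1831 ± 590 TPM), and Aldh9a1 lower (-0.67). When adjusted over the list alone 7 were higher and 1 lower (0.0170, and adjusted p = 0.515 with an estimated correlation). Circadian clock genes had 5 of 17 higher, among them Tef (1.97), and Arntl lower, with 7 and 1 when adjusted over the list alone (0.0170, and adjusted p = 0.297 with an estimated correlation). PPAR-alpha targets had 4 of 29 higher, among them Cyp4a10 (4.55) and Acaa2 (0.86), and 7 when adjusted over the list alone (0.00472, and adjusted p = 0.515 with an estimated correlation). ER stress genes had 3 of 24 higher, Sesn2, Creld2 and Ern1, all listed at 0 on control diet (0.00295, and adjusted p = 0.477 with an estimated correlation). Immediate-early genes were lower as a list, with Fos and Egr1 (-2.94) past the test and Maff higher (1.83). Its counts were 9 lower and 1 higher when adjusted over the list alone (0.0170, and adjusted p = 0.515 with an estimated correlation). Of the 25 HMGB1 and IL-1 receptors and ligands none passed (camera adjusted p = 0.822). Other passing genes were Thrsp (876 ± 90.5 against 148 ± 66.8 TPM), Plin2, which fell from 338 ± 146 to 74.5 ± 18.2 TPM (-2.11), and Cyp8b1, which fell from 201 ± 19.0 to 55.5 ± 41.4 TPM (-2.31).

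**Figure D4:**
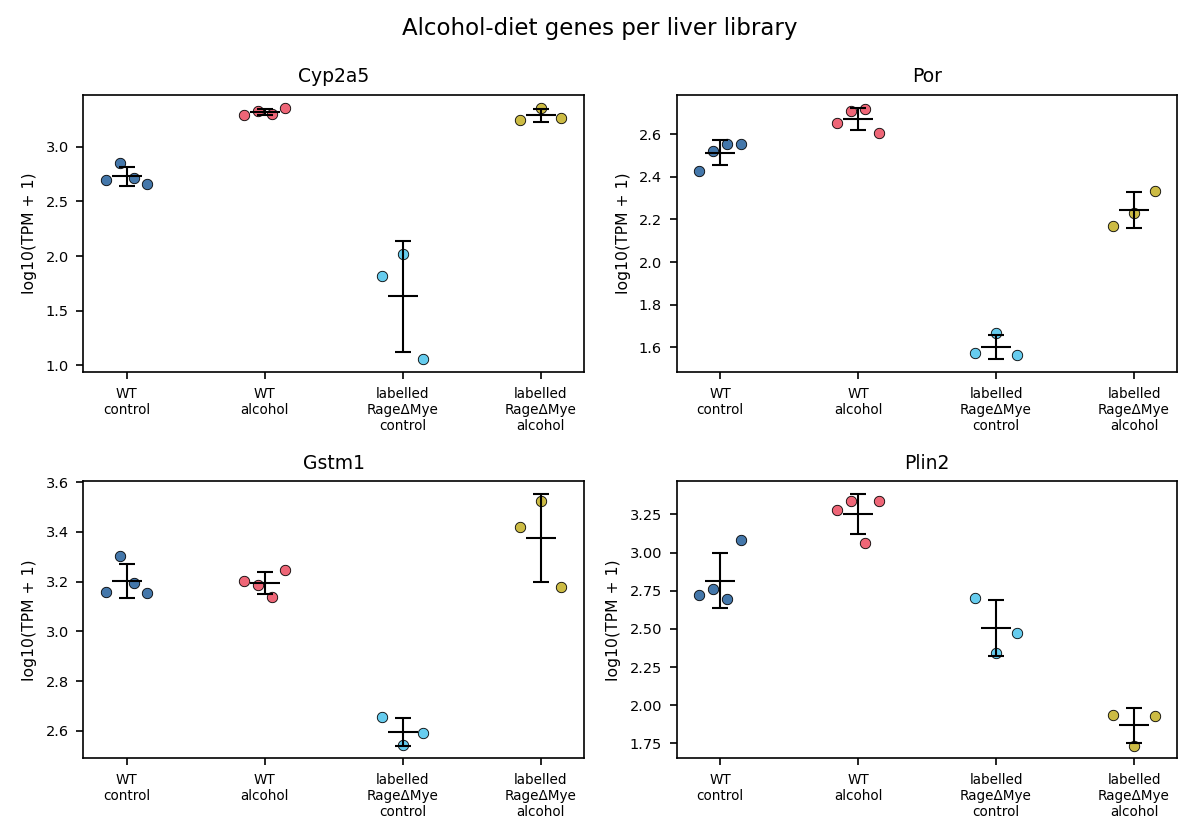
Cyp2a5, Por, Gstm1 and Plin2 as log10(TPM + 1) in the 14 liver libraries by group, with points for libraries and bars for mean ± SD of the log values. Cyp2a5 lies at 10.4 to 103 TPM in control and 1764 to 2236 TPM in alcohol libraries labelled RageΔMye.

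The joint fit called 657 of 12069 genes in the libraries labelled RageΔMye, 345 higher and 312 lower, but it lends them the narrower spread of the WT libraries. A fit of the 6 libraries alone called 4 genes at adjusted p under 0.05 and 747 at unadjusted p under 0.05. The 4 were Cyp4a14 (adjusted p = 0.0157), Mup20 (0.0177), Pitx3 (0.0360) and Tomm40l, chosen after its values were seen. Tomm40l lies on the opposite strand to the nuclear receptor gene Nr1i3 and rose from 3358 ± 931 to 22144 ± 3474 TPM (2.75, adjusted p = 0.0157). Cyp2a5 (adjusted p = 0.0630) and Por (0.102) did not pass in that fit. With library weights per genotype, chosen after seeing the data, 50 genes passed. Of the genes named here only Pitx3 (adjusted p = 1.8e-05) and Cyp2a5 (0.0184) were among them, and Tomm40l (0.154), Mup20 (0.278), Por (0.387) and Cyp4a14 (0.575) were not. No overlap between the diets was seen for 1258 genes (10.4%), against 10% by chance, and without the alcohol replicate 3 the joint fit called 1110 genes.

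Genes called in both genotypes were few. Between the 173 rises in WT liver and the 345 in libraries labelled RageΔMye, 6 genes were shared (4.95 would be shared by independent lists, Fisher's exact test, one-sided, adjusted p = 0.374). Between the falls 16 were shared, with 4.21 for independent lists (adjusted p = 9.7e-06). Of the 36 genes called in both, 14 moved in opposite directions, among them Plin2 and Aldh1a1. Across genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.0777 and a Spearman correlation of -0.0182. With fits of each pair of groups alone, chosen after seeing the data, 1 rise and 1 fall were shared.

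The difference of the alcohol effect between genotypes was tested directly. It passed for Cyp2d9, which fell in WT liver but lay at 474 ± 268 and 441 ± 128 TPM on alcohol and control diet in libraries labelled RageΔMye (difference of log2 fold changes 6.37, SE 0.505, adjusted p = 1.4e-05). It also passed for Mup8 (8.47), Cyp4a12a (6.39), Mup12 (6.14) and Fam47e (5.92). It passed in the other direction for Cyp3a41a (-8.82), Sult2a2 (-8.42), Sult2a1 (-8.11), Cyp2c40 (-7.97) and Cyp2c69 (-7.24), all but Sult2a2 members of the female-biased list. Except for Cyp2c40, at 24.5 TPM in 1 control library, these were listed at 0 in all libraries labelled RageΔMye, so that their values are those of WT liver. Plin2 (-3.57, SE 0.519, adjusted p = 0.00155), Aldh1a1 (2.20, adjusted p = 0.00137), Cyp2e1 (1.45, adjusted p = 0.0127), Por (1.61, adjusted p = 0.00262) and Gstm1 (2.62, adjusted p = 4.0e-04) differed in their response in the joint fit. Among the acute-phase genes Fgg (-1.99) and Fgb (-1.90) did. Since the WT diet groups also differ in Xist and in the Y-linked sum, sex cannot be told apart from genotype in these differences. For the genes of the labels the difference did not pass, Il1rn being nearest (-3.13, SE 0.820, adjusted p = 0.0565), followed by Il1r1 (-1.12), Il1rap (0.28), Il1b (-0.82), Ager (-0.04) and Hmgb1 (0.03).

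Of the female-biased genes 10 of 18 passed with a lower response in libraries labelled RageΔMye, and 13 when adjusted over the list alone (camera adjusted p = 2.0e-15, and adjusted p = 0.0374 with an estimated correlation). Of the male-biased genes 8 of 17 had a higher response, and 9 when adjusted over the list alone (8.6e-09, and adjusted p = 0.108 with an estimated correlation). Both lists are those that moved with Xist and the Y-linked sum in WT liver. Of the HMGB1 and IL-1 receptors and ligands 1 of 25 had a lower response, Il1r2 (-1.57), listed at 0 in all libraries labelled RageΔMye, and 3 when adjusted over the list alone (camera adjusted p = 0.00808, and adjusted p = 0.0938 with an estimated correlation). In all 7 lists were higher and 10 lower at the preset correlation, of which only the female-biased list held with an estimated one. The joint fit called 463 of 12069 genes, 250 higher and 213 lower. With library weights per genotype, chosen after seeing the data, it called 61. Of the 18 genes named here with a difference that passed, only Cyp2d9 (adjusted p = 0.00162), Mup8 (0.0161) and Cyp2c69 (0.0254) then passed. The other 15 did not, namely Cyp4a12a (adjusted p = 0.0638), Fam47e (0.120), Cyp2c40 (0.148), Mup12 (0.178), Gstm1 (0.215), Sult2a1 (0.376), Sult2a2 (0.432), Aldh1a1 (0.478), Cyp2e1 (0.478), Por (0.527), Cyp3a41a (0.544), Plin2 (0.585), Il1r2 (0.712), Fgg (0.749) and Fgb (0.759). Without WT alcohol replicate 1 the joint fit called 282 genes, and without the alcohol replicate 3 labelled RageΔMye it called 899.

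Libraries labelled RageΔMye were compared with WT libraries on each diet. The names of the samples have 1 prefix in WT and another in the libraries labelled RageΔMye, so genotype and any batch behind the names cannot be told apart. The median log2 fold change of all tested genes was -0.50 on alcohol and -0.59 on control diet, and the fold changes in this comparison are given relative to these medians. The adjusted p-values, calls and counts belong to the fold changes before this shift. Ager was higher by 7.18 on alcohol and 7.32 on control diet (adjusted p = 7.7e-11 and 7.6e-11), against the label. Il1rap, the accessory protein of the IL-1 receptor, was at 680 ± 112 against 10.5 ± 3.17 TPM on alcohol (6.42) and at 839 ± 32.9 against 16.0 ± 2.48 TPM on control diet (6.23). Its exons overlap exons on the opposite strand. Genes with such an overlap held more of the TPM in libraries labelled RageΔMye than in WT. Il1r1 was lower, by -4.39 and -3.17. Hmgb1 (0.88 and 0.94, or 0.38 and 0.35 as tested, before the shift) and Il1b did not pass on either diet. Il1rn was listed at 0 in the alcohol libraries labelled RageΔMye against 9.86 ± 4.43 TPM in WT. The largest differences were in Snx22, at 19982 ± 2166 against 0.258 ± 0.0114 TPM on alcohol and 17539 ± 2684 against 0.160 ± 0.0606 TPM on control diet. Other large ones were Eyelinc18 (14756 ± 1361 against 0.388 ± 0.232 TPM on alcohol), Tomm40l (13.23), Tmem206 (12.59) and, on control diet, Cnbd2 (11.99). Mir6340 was at 3048 ± 1140 TPM against 0 on alcohol. Lower was Mir6236 (listed at 0 against 14664 ± 1778 TPM on alcohol and 13483 ± 5229 TPM on control diet). Lower as well were the metallothionein genes Mt2 (-8.64) and Mt1 (-6.83) on control diet, the haemoglobin gene Hba-a2 and Rgs16 (both listed at 0 on control diet). On alcohol the same held for Cyp3a41a, Sult2a2 and Sult2a1, which were listed at 0 against WT libraries with 17.8 TPM or more of Xist. Unlike Hba-a2, the haemoglobin gene Hba-a1 was higher, by 6.04 on control diet and by 3.39 on alcohol.

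Hepatocyte markers were lower on both diets, 20 of 23 on alcohol and again 20 on control diet, where 1 was higher. The albumin gene Alb was at 21987 ± 823 against 120620 ± 7636 TPM and 25424 ± 4084 against 101570 ± 10145 TPM. Their camera adjusted p was 1.4e-05 and 1.4e-04, and adjusted p = 0.0526 and 0.0748 with an estimated correlation. The same counts were found over the list alone. Of the oxidative phosphorylation genes 19 and 23 of 26 were lower, among them Sdha and Atp5a1, and 20 and 24 when adjusted over the list alone (5.7e-04 and 1.4e-04, and adjusted p = 0.218 and 0.170 with an estimated correlation). Of the acute-phase genes 23 and 21 of 26 were lower, among them Hamp (-1.25 and -0.94), and of the PPAR-alpha targets 20 and 22 of 29. Cell cycle genes had 4 higher and 5 lower of 19 on alcohol and 6 and 5 on control diet (camera adjusted p = 0.277 and 0.109), with the mitotic kinase gene Aurka at 236 ± 47.2 against 0.518 ± 0.141 TPM on alcohol. On alcohol 16 of 18 female-biased genes were lower (camera adjusted p = 1.3e-05, and adjusted p = 0.218 with an estimated correlation). Of the male-biased genes 5 of 17 were higher (0.0443, and adjusted p = 0.472 with an estimated correlation), against WT libraries that hold Xist and lack Y-linked transcripts. In all 1 list was higher and 14 lower on alcohol and 9 lower on control diet, and none of them passed with an estimated correlation. The list counts come from TPM that were not rescaled. Genes with an opposite-strand overlap held 57.8% to 63.7% of the TPM in libraries labelled RageΔMye and 15.4% to 18.3% in WT. For the lists, how much of the lower counts goes with these shares was not tested. Over all genes the excess of lower over higher calls was smaller when overlapping genes were left out and TPM rescaled, as given below.

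On alcohol 6079 of 12069 genes passed, 2276 higher and 3803 lower, and on control diet 6352, 2229 higher and 4123 lower. No overlap between genotypes was seen for 57.7% and 55.7% of genes, against 5.71% by chance. Without the genes that overlap exons on the opposite strand, an alternative chosen after seeing the data, the share of higher genes went from 37.4% to 23.9% on alcohol (901 higher and 2874 lower) and from 35.1% to 21.8% on control diet (865 higher and 3099 lower). With TPM rescaled over the genes left, 3059 genes passed on alcohol (1394 higher and 1665 lower) and 3079 on control diet (1355 higher and 1724 lower).

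The last comparison asked what the complex of [O] HMGB1 and IL1β changed in RAW264.7 cells. The largest rises among the named genes were in inflammatory genes. Tnf, on chromosome 17, rose from 374 ± 90.6 to 2291 ± 142 TPM (log2 fold change 2.64, SE 0.187, adjusted p = 0.00364), and the neutrophil chemokine gene Cxcl2 from 8.97 ± 3.82 to 87.7 ± 9.37 TPM (3.21, SE 0.349, adjusted p = 0.0263). The itaconate-producing Acod1 rose from 27.1 ± 9.74 to 236 ± 7.32 TPM (3.15, SE 0.307, adjusted p = 0.0151), and Marcksl1 from 106 ± 25.2 to 426 ± 82.4 TPM (2.00, SE 0.235, adjusted p = 0.0333). Il1b was listed at 0 in the 3 BSA libraries and rose to 25.9, 36.1 and 16.9 TPM (adjusted p = 0.0300). The other named rises were Nfkbil1 (2.22), Tmem132a (2.15), Ddx28 (2.14), Xcr1 (1.67) and Jdp2 (1.46). The 3 falls were Oraov1, from 13136 ± 667 to 5253 ± 235 TPM (-1.32, SE 0.0609, adjusted p = 9.2e-04), the prostacyclin receptor gene Ptgir, from 435 ± 38.7 to 191 ± 22.8 TPM (-1.19), and Layn, from 19.6 ± 3.02 TPM to 0 in all 3 libraries. Exons of Il1b, Nfkbil1, Tmem132a, Ddx28, Jdp2 and Oraov1 overlap exons on the opposite strand, and such genes held 72.3% to 76.1% of the TPM in RAW264.7 libraries. Whether the changes listed for these genes belong to them or to the genes opposite was not tested. Il1rn was at 32.4 ± 19.8 against 15.3 ± 6.22 TPM (0.85, adjusted p = 0.755), Hmgb1 at 102 ± 26.2 against 81.3 ± 15.1 TPM (0.31, adjusted p = 0.755). Il1rap was at 0.146 ± 0.253 against 1.24 ± 1.08 TPM (-0.89, adjusted p = 0.753), and Il1r1 and Ager were listed at 0 in all 6 libraries.

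Of the cytokines and chemokines 3 of 24 rose, and 10 when adjusted over the list alone (camera adjusted p = 4.6e-14, and 0.0234 with an estimated correlation). Of the pro-inflammatory macrophage genes 4 of 13 rose, and 7 when adjusted over the list alone (5.4e-12, and 0.0326 with an estimated correlation). None of the 26 NF-kB targets passed among all genes, but 12 were higher when adjusted over the list alone (4.5e-14, and 0.0234 with an estimated correlation). Tnfaip2 was at 98.1 ± 16.8 against 25.9 ± 4.55 TPM (adjusted p = 0.0527) and Tnfaip3 at 33.3 ± 8.48 against 4.69 ± 1.88 TPM (adjusted p = 0.0820). The inflammasome list was higher, with Il1b its only passing member of 9 and 2 when adjusted over the list alone (0.0374, and adjusted p = 0.40 with an estimated correlation). The cell cycle list was lower, with none of 29 passing, even over the list alone, and E2f1 at 2.03 ± 1.78 against 8.69 ± 3.09 TPM (0.0374, and adjusted p = 0.633 with an estimated correlation). The HMGB1 and IL-1 list did not pass (1 of 21 rose, Il1b, camera adjusted p = 0.507), and its median of -0.01 and mean of 0.02 differed in sign.

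**Figure D5:**
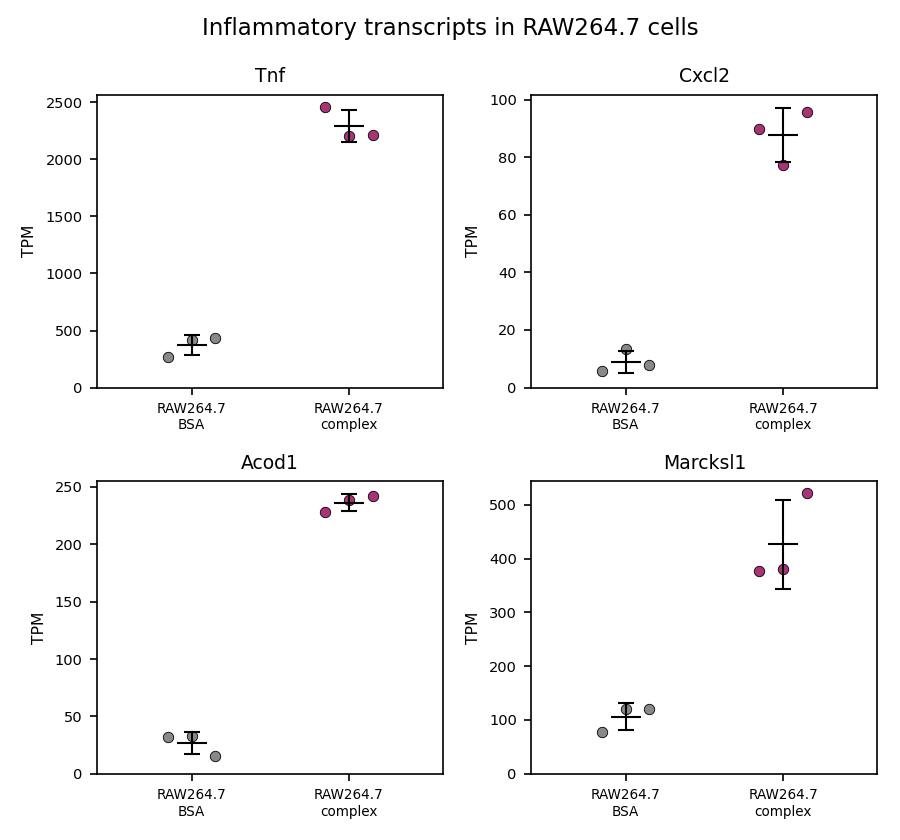
TPM of Tnf, Cxcl2, Acod1 and Marcksl1 in the 3 BSA and 3 complex libraries of RAW264.7 cells, with points for libraries and bars for mean ± SD. Tnf lies at 270 to 437 TPM with BSA and at 2204 to 2455 TPM with the complex.

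In all limma called 19 of 10559 genes, 16 higher and 3 lower, and 877 had an unadjusted p under 0.05. Exons of 11 of the 19 overlap exons on the opposite strand (57.9%, against 35.8% of tested genes), and without such genes 3 passed, an alternative chosen after seeing the data. No overlap between treatments was seen for 1429 genes (13.5%), against 10% by chance, and the count was 2 without complex replicate 2 and 9 without BSA replicate 2. None of the genes called in RAW264.7 cells was called in the same direction in WT liver by the joint fit. Independent lists would share only 0.113 among rises and 0.0123 among falls, so that 0 says little (Fisher's exact test, one-sided, adjusted p = 1 for both). With WT liver fitted alone, an alternative chosen after seeing the data, 4 rises were shared, with 0.776 for independent lists, and 0 falls.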

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

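The tests of opposite-strand reads, sequencing depth, shared exons, sex and exchanged labels were chosen only after the patterns had been seen. The tests of the myeloid deletion, of the RAW264.7 partners, of convergent genes and of other groupings of the libraries had their predictions written before their values were computed.

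Libraries labelled RageΔMye list high TPM for genes near 0 in WT liver, with 408 of the 14634 genes under 1 TPM in all 8 WT libraries at 10 TPM or more in all 6 of them. Exons of 77.5% of these overlap exons on the opposite strand, against 17.1% of other genes, and in RAW264.7 cells 7 of the 8 opposite-strand partners of inflammatory list genes were higher (1 passed), with a median log2 fold change of 1.09, against 0.389 at the upper bound of 10000 random sets. Lower depth would not raise 408 genes in every library, and against a deletion of Ager stands that 71.1% of these genes also reach 10 TPM in all 3 RAW264.7 BSA libraries (2.69% of other genes). Reads counted on the opposite strand in these libraries are a candidate explanation, and the strand setting stays open. The 63 genes under 1 TPM in WT with an abundant opposite-strand partner had a median of 6.79 TPM in libraries labelled RageΔMye. This lies between the bounds of 10 and 1 TPM written for that test, so the test does not decide. Of these genes 44.4% reached 10 TPM there, against 1.49% of 12179 genes without such an overlap, whose median was 0. Their levels there had a Spearman correlation of -0.0296 with the level of the partner in WT. With the level of the partner in libraries labelled RageΔMye it was 0.102. If reads were counted on the opposite strand there, the listed level of the partner would be affected too, so this second value cannot decide. Neither correlation takes into account how many bases overlap.

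In all 8 WT libraries Xist and the Y-linked genes split by diet group. The summed Y-linked TPM of the alcohol group was 0.0362% of that of the control group, which argues against an effect of alcohol in animals of 1 sex. Animals of a different sex in the diet groups are consistent with these values, against the label. How much of any difference between the WT diet groups belongs to the diet stays open, since sex and diet cannot be separated in these libraries. This holds for the sex-biased genes as well as for the inflammatory, matrix and metabolic genes.

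Ager lay on the side of the other genotype label in all 14 liver libraries. Among genes under 1 TPM in WT liver without an exon overlap, some face an abundant convergent neighbour within 1 kb on the opposite strand. These reached 10 TPM in libraries labelled RageΔMye 14.4 times as often as those without such a neighbour (8 of 39, Ager not counted, against 173 of 12139, Fisher's exact test, one-sided, p = 8.5e-08). Ager has such a neighbour, Rnf5, at 154 bp, so reads of Rnf5 are a candidate explanation. In RAW264.7 libraries, where genes with an opposite-strand overlap held 72.3% to 76.1% of the TPM, Ager nevertheless held none. Exchanged labels and this reading cannot be told apart by Ager itself, so whether myeloid cells lost Ager stays open.

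Some single libraries lay far from the others of their group, which chance does in about 1 in 20 groups, or 7.2 of the 144 tested, against 17 found. WT control replicate 2 was high for Cyp2a4 (10.6 TPM), Cyp3a41a (13.3 TPM), Sult2a2 (7.39 TPM), Sult2a1 (4.71 TPM), Cyp2b9 (6.29 TPM), A1bg (4.81 TPM), Cyp2b13 (3.51 TPM) and Gbp3 (2.54 TPM), and replicate 1 for Mup1 (4953 TPM). WT control replicate 4 was low for Gstp1 (1702 TPM) and high for Lyve1 (6.89 TPM), Cd36 (13.5 TPM) and Plin2 (1215 TPM). WT alcohol replicate 4 was high for Mup7 (15.0 TPM) and Gbp3 (11.6 TPM), and WT alcohol replicate 3 was low for Il1r1 (59.3 TPM) and above 0 for Cyp4a12b (0.0533 TPM).

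The alcohol effect differed between the genotypes as labelled, by a direct test with limma in the joint fit, for 463 genes. In simulated data with each group's own spread 77.4% of the calls for this difference were false. The WT diet groups also differ in Xist and Y-linked transcripts, and genotype goes with the prefix of the sample names. Neither can be told apart from genotype in any of these differences. The differences of log2 fold changes were 8.47 for Mup8, 6.39 for Cyp4a12a, 6.37 for Cyp2d9, 6.14 for Mup12 and 5.92 for Fam47e. They were -8.82 for Cyp3a41a, -8.42 for Sult2a2, -8.11 for Sult2a1, -7.97 for Cyp2c40 and -7.24 for Cyp2c69. All of these 5 but Cyp2c40 were listed at 0 in all libraries labelled RageΔMye, so their values are those of WT liver, where the diet groups also differ in Xist and Y-linked transcripts. Further differences were -3.57 for Plin2, 2.62 for Gstm1, 2.20 for Aldh1a1, 1.61 for Por, 1.45 for Cyp2e1, -1.99 for Fgg, -1.90 for Fgb and -1.57 for Il1r2. With library weights per genotype 61 genes passed, and of the genes in this paragraph only Cyp2d9, Mup8 and Cyp2c69 did, while Cyp3a41a (adjusted p = 0.544), Sult2a2 (0.432) and Sult2a1 (0.376) were among those that did not. The female-biased list had a median difference of -3.27.

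The same libraries were also split in other ways. In WT liver 1 of 35 splits, the real one, called as many as 337 genes, and the highest other called 1. Every other split put libraries that differ in Xist and in Y-linked transcripts into the same group. Their low counts therefore say little about chance, and the split does not separate diet from sex. For genotype the real split was the 1 of 35 with 6079 genes on alcohol and 6352 on control diet, and for the difference of effects the 1 of 100 with 463 genes. The highest other counts were 2166, 2365 and 319. For genotype, other splits called genes only where the 3 libraries labelled RageΔMye stayed together beside 1 WT library, and every split that mixed them called 0. For the difference of effects the highest other count came from a split that differed from the real one, with its groups exchanged, in 2 libraries. With 3 libraries against 3 only 10 splits exist, too few to exclude chance. In libraries labelled RageΔMye the real split called 657 genes, but every other split also called genes, 162 to 342 of them. The joint fit thus called many genes there under any grouping. In RAW264.7 cells the real and highest other counts were 19 and 1.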

How the results depend on the processing

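Variants that need counts were not run because the unit is TPM. The alternatives without opposite-strand overlaps, with quantile normalization and with library weights, and the relations between fits of 2 groups, were chosen after seeing the data. Of 3810 alternative values for 217 named gene results, 3145 kept their side of the threshold, 646 were weaker and 19 stronger. Reversed were 0, counted only where the gene passed in the main or the alternative fit. In WT liver on alcohol the count of 337 became 1053 without a filter, 147 at an adjusted p under 0.01, 3042 with only the libraries compared and 3553 with library weights. Leaving out 1 library gave 164 (WT control replicate 3) to 360 (WT control replicate 4). In libraries labelled RageΔMye the count of 657 became 362 at a pseudocount of 0.01, 272 at an adjusted p under 0.01, 4 with only the libraries compared, 50 with library weights and 403 without overlapping genes. Leaving out 1 library gave 823 (alcohol replicate 2) to 1110 (alcohol replicate 3). Fewer tested genes account in part for the counts without overlapping genes, which for genotype were 3775 on alcohol and 3964 on control diet, and 3059 and 3079 with TPM rescaled. For the difference of effects the count of 463 became 219 at an adjusted p under 0.01, 61 with library weights, 291 without overlapping genes and 268 with TPM rescaled, and 282 (WT alcohol replicate 1) to 899 (alcohol replicate 3 labelled RageΔMye) with 1 library left out. In RAW264.7 cells the count of 19 became 7 at an adjusted p under 0.01 and 3 without overlapping genes, and 2 (complex replicate 2) to 9 (BSA replicate 2) with 1 library left out. With the sample number as a replicate block the count was 0 in a fit of only the libraries labelled RageΔMye, which called 4 without the block. In RAW264.7 cells the count with this block was 0. Deviations of libraries with the same number correlated across genes at 0.0181, -0.0163 and -0.000201 in libraries labelled RageΔMye. In RAW264.7 cells they correlated at -0.00111, -0.0254 and -0.0132, so the numbers showed no pairing. Of the lists, 21 in WT liver became 9 with an estimated correlation and 13 with fry, 8 in libraries labelled RageΔMye became 0 with an estimated correlation, 17 for the difference became 1, and 5 in RAW264.7 cells became 3 with either. For genotype 15 and 9 lists became 0 and 0 with an estimated correlation and 30 and 31 with fry. With fits of 2 groups, 1 rise and 1 fall were shared between genotypes in place of 6 and 16, and 4 rises between RAW264.7 cells and WT liver in place of 0. Elsewhere the cause was not tested. The depth of the libraries is unknown, so the lowest level that could be seen is unknown as well.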

Other observations

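The tests named in this part were planned before the data were examined, and the choice of which genes to describe followed the same rule as in the results. In libraries labelled RageΔMye on alcohol (n = 3 per group, limma, Benjamini-Hochberg), genes of methionine metabolism rose, Ahcy from 250 ± 33.7 to 456 ± 33.3 TPM (log2 fold change 0.87, adjusted p = 0.00264), Gnmt (0.77) and Mat1a (1.15), although the list did not pass (camera adjusted p = 0.0597). The glycolytic genes Aldoa (1.64), Gpi1 (1.55) and Tpi1 (0.90) rose. The fatty acid desaturation and elongation genes Elovl5 (-2.21) and Fads2 (-1.62) fell, as did the droplet coat gene Plin4 (-2.27). Among macrophage genes the scavenger receptor Msr1 was listed at 0 on control diet and rose to 11.9 ± 4.41 TPM, and the Kupffer cell genes Clec4f (-1.90) and C6 (-2.98) fell. The matrix genes Vim and Col3a1 were listed at 0 on alcohol, from 9.17 ± 6.70 and 2.66 ± 0.929 TPM. These calls come from the joint fit, and none of them passed in a fit of the 6 libraries alone or with library weights, an alternative chosen after seeing the data.

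In WT liver on alcohol (n = 4 per group) the cyclin gene Ccnd1 rose from a mean of 14.2 to 47.5 TPM (log2 fold change 1.70, adjusted p = 0.0234), the only passing member of the cell cycle list. The clock repressor Nr1d1 (-0.96), the haem synthesis gene Alas2 (-2.65) and the hepatocyte genes Cyp2f2 (-1.28) and Serpina1c (-0.76) fell. Between libraries labelled RageΔMye and WT libraries the alcohol dehydrogenases went opposite ways, with Adh7 at 406 ± 68.2 against 2.26 ± 0.307 TPM and Adh5 at 94.9 ± 13.4 against 432 ± 18.6 TPM on alcohol. Genotype cannot be told apart here from any batch behind the sample names. The 2 sets of libraries also differ in the share of TPM held by genes with an opposite-strand overlap. In RAW264.7 cells (n = 3 per group) the ER stress gene Herpud1 was at 83.2 ± 17.2 against 22.1 ± 4.30 TPM (adjusted p = 0.0635), and the NRF2 target Osgin1 was listed at 0 with the complex against 14.2 ± 4.87 TPM (adjusted p = 0.0527).

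Some genes of RAW264.7 cells were chosen after their values were seen. Oraov1 lies opposite to Ccnd1, which was at 161 ± 2.24 against 201 ± 13.2 TPM (adjusted p = 0.589), and Tmem132a lies opposite to Slc15a3 (log2 fold change 1.56, adjusted p = 0.0841). Gm14023, opposite to the cytokine gene Il1a, had a log2 fold change of 7.99 (adjusted p = 0.00698).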
